A study of Mus musculus with 7 samples.

How the data were processed

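RNA was measured in whole colon tissue of 7 C57BL/6 mice that drank 2.5% dextran sulfate sodium (DSS), a detergent-like polymer that injures the colonic epithelium, for 5 days. There were 4 wild-type (WT) mice and 3 mice with loxP-flanked Uhrf1 and a Cre recombinase driven by the myeloid gene Lyz2 (conditional knockout, cKO). Groups and replicate numbers come from the labels. Numbers 1, 3 and 4 occur in both groups and 2 in wild type alone. The design text counts mice per group, so each library was taken as 1 mouse. Untreated colons were not analysed here.

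Total RNA went into libraries made with a NEBNext Ultra kit, per the labels' protocols. The deposited values are raw counts per Ensembl gene, whole numbers with a different total in each library, with a column name ending in the word count per the file headers. The submitters' processing notes name bcl2fastq 2.19, TopHat2 2.1.0, Cufflinks 2.2.1 and the build mm10, without saying which step each served. The counting program, the annotation release and the strand setting are not given in the sources used here. Reads from overlapping genes, from antisense partners and from near-identical paralogs may therefore be divided in ways that cannot be checked, and values of Serpina3m, Serpina3n, Gstm3, Cyp2c65, Mettl7a2, Ugt1a1, Ugt2b35 and the H2 genes carry that uncertainty. The tables hold 54532 genes, of which 54409 matched a symbol in the reference table of gene names. Coordinates are from the GENCODE annotation of the same build.

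Library totals ran from 15212281 to 18258833 counts. A count of 0 in a library allowed a level of up to 0.153 to 0.211 CPM (3 counts of the library's effective size), and floors and count intervals (95%) cover counting error only. Within each group every pair of libraries differed by far more than sampling noise, with a chi-square per degree of freedom of 35.2 to 215 over genes with at least 20 counts in the pair, so no library was counted as a duplicate.

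Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr (minimum count 10, minimum total 15) were kept, which left 15940, and libraries were scaled by TMM. The quasi-likelihood test (glmQLFit and glmQLFTest, two-sided, no covariate) compared cKO with WT, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM, given as mean ± SD. A gene with 0 counts throughout a group was given a bound computed against 3 counts over that group, and one with 1 to 3 counts a ratio with an exact binomial interval.

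Of 35 gene lists fixed before the data were examined, 32 had at least 5 tested members and were compared with all other genes by camera (limma 3.58.1, preset inter-gene correlation 0.01, log2 CPM with prior count 2). The lists were also tested by camera with an estimated correlation, by fry, and by an exact two-sided permutation test of the mean log2 CPM per library over the 35 splits of 7 libraries into 4 and 3, whose smallest possible p is 0.0286. Il36a and Il36g of the cytokine list were matched through the older names Il1f6 and Il1f9. The germline list (3 tested members), the pancreas and small intestine list (4) and the sex-linked list (4) were not tested as lists.

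The genes named were chosen by a rule set before the data were examined. It took Uhrf1 and Tnf, then the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, leaving out predicted genes, immunoglobulin and T cell receptor segments and pseudogenes. It added the 3 members with the smallest p of each list past the camera threshold and of the cytokine, NF-kB, macrophage and neutrophil lists, and up to 3 passing members of other lists. Genes named outside it are said to have been chosen after their values were seen.

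The procedure was tested on simulated counts with the real means and library sizes. Over 15594 genes it recovered 46 of 100 genes changed 4-fold and 5 of 100 changed 2-fold, with 53 calls, 2 of them false. Changes near 2-fold were thus mostly missed in the simulation. The adjusted threshold is less strict where more genes change, and 992 passed in the real data, so this recovery need not carry over. Alternatives planned beforehand were no filter, a filter at a mean of 2 CPM, DESeq2 size factors, upper-quartile factors, the DESeq2 1.42.0 Wald test, voom with quality weights, the replicate number as a block, and each library left out in turn. Robust moderation, a threshold of 0.1 and leaving out X and Y chromosome genes were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.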

Results

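Gene expression was measured by RNA sequencing of whole colon from 4 wild-type mice and 3 Uhrf1 conditional knockout mice, all given 2.5% DSS for 5 days. Library totals were 16249253, 17027022, 17132912 and 18258833 counts in WT 1 to WT 4, and 16624601, 15212281 and 16363714 counts in cKO 1, cKO 3 and cKO 4. The comparison asks how loss of Uhrf1, a protein that guides DNA methylation to newly replicated DNA, in myeloid cells alters the inflamed colon.

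Uhrf1 itself (ENSMUSG00000001228, mm10 chromosome 17, 56303321 to 56323486, plus strand) stood at 11.7 ± 7.57 CPM (SD, n = 4) in wild type and 2.97 ± 0.616 CPM (SD, n = 3) in the conditional knockout. The groups did not overlap, and the log2 fold change was -1.98 (SE 0.49). This did not pass the edgeR quasi-likelihood test (adjusted p = 0.0521). An exact permutation test of log2 CPM gave p = 0.0286, the smallest that the 35 splits allow. The deletion was directed at myeloid cells, whereas the RNA came from the whole tissue. Lyz2, whose promoter drives the Cre, was at 1200 ± 260.3 CPM in wild type and 1229 ± 247 CPM in the conditional knockout. Without WT 4 the adjusted p of Uhrf1 was 0.0482, and with DESeq2 it was 0.00102 at a log2 fold change of -2.01. Over all alternatives it ran from 0.00102 to 0.193.

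Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007, minus strand), which encodes the cytokine tumour necrosis factor, was at 20.1 ± 8.42 CPM (n = 4) in wild type and 52.4 ± 27.1 CPM (n = 3) in the conditional knockout. The log2 fold change was 1.38 (SE 0.45), the groups overlapped, and neither the edgeR test (adjusted p = 0.104) nor an exact permutation test (p = 0.114) passed. Without cKO 4 the adjusted p was 0.0385, and it was 0.0417 with DESeq2 and 0.00714 with voom quality weights, where the log2 fold change was 2.04. Over all alternatives the adjusted p ran from 0.00714 to 0.350.

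Il6, Cxcl3, Mmp13 and Serpina3n were among the genes that rose in the conditional knockout, and Vil1, Cd74 and Mki67 among those that fell. Of 15940 genes tested, 992 passed at an adjusted p of 0.05, 362 higher and 630 lower, and 178 of the former and 188 of the latter changed at least 4-fold. The groups did not overlap for 988 of the 992. Among all tested genes the groups did not overlap for 25.7%. The share expected by chance is 5.71% on average over splits. Genes move together, so a single chance split can lie far from that, and the share in the other splits was not computed. The smallest adjusted p was 0.00125, and 742 of the 992 lay between 0.03 and 0.05. The count depended on single libraries. It was 3 without WT 1, 2 without cKO 1, 3 without cKO 3, 380 without WT 2 and 1608 without cKO 4, and the count of higher genes was 211 without WT 3.

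**Figure D1:**
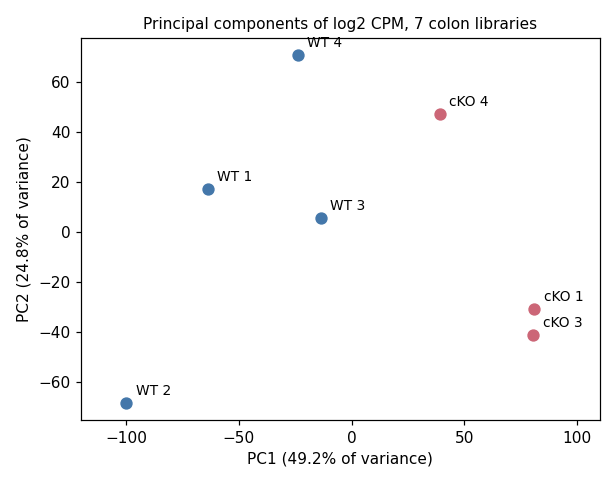
Principal components of log2 CPM over the 15940 tested genes. The horizontal axis is PC1 (49.2% of variance), the vertical axis PC2 (24.8% of variance), and each point is 1 library (blue, wild type; red, conditional knockout). On PC1 all wild-type libraries lie below 0 and all conditional knockout libraries above it, with cKO 4 at 39.3 and cKO 1 and cKO 3 at 81.1 and 80.7.

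The libraries also differed in other ways that ran with the groups or within them. cKO 4 held 2495 Xist counts and none of Ddx3y, Uty, Kdm5d or Eif2s3y, while the other 6 libraries held at most 3 Xist counts and at least 815 Ddx3y counts, so that 1 library came from a female and 6 from males. Hoxb13 (ENSMUSG00000049604, chromosome 11, 96194316 to 96197447, plus strand), a homeobox gene of the hindgut chosen here after its values were seen, fell from 279 ± 76.6 CPM to 46.3 ± 25.04 CPM (log2 fold change -2.59, adjusted p = 0.0271 by edgeR). The share of counts from mitochondrial genes was 4.21 ± 1.14% (n = 4) in wild type and 2.35 ± 0.441% (n = 3) in the conditional knockout (exact permutation p = 0.0571, adjusted p = 0.143 over 5 library measures).

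Among the named genes with more than 3 counts in each group, Serpina3m (ENSMUSG00000079012, chromosome 12, 104338486 to 104394257) had the largest rise, from 0.490 ± 0.185 to 54.7 ± 16.0 CPM, a log2 fold change of 6.79 (SE 0.37, adjusted p = 0.00125). Its neighbour Serpina3n (ENSMUSG00000021091, chromosome 12, 104406729 to 104414329), an acute-phase protease inhibitor, rose from 27.1 ± 8.37 to 759.6 ± 174 CPM (4.81, SE 0.34, adjusted p = 0.00425). Both belong to a family of similar genes between which reads may be divided. Prl2a1 and Trh had no counts in wild type and 157 and 122 counts in the conditional knockout, at least 67.4-fold and 52.4-fold higher against 3 counts over the wild-type group. Wfdc12 had 3 counts in wild type and 219 in the conditional knockout, a ratio of 94.1 with a counting interval of 31.8 to 459.7. It was at 8.90 CPM in cKO 1 against 0.954 and 2.76 CPM in cKO 3 and cKO 4. Its log2 fold change of 6.34 went to 5.17 without cKO 1 and 7.23 without WT 3. The other large rises were in Csf3 (log2 fold change 5.82), Cxcl3 (5.77), Il6 (4.96), Lrrc2 (4.79), Ccl4 (4.74), Il1r2 (4.72) and Mmp10 (4.71). Without WT 3 the log2 fold changes of Csf3, Cxcl3, Il6 and Ccl4 were 7.52, 6.74, 6.54 and 6.11, and that of Csf3 then exceeded that of Serpina3m (6.99), so the order of the largest rises depends on WT 3.

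**Figure D2:**
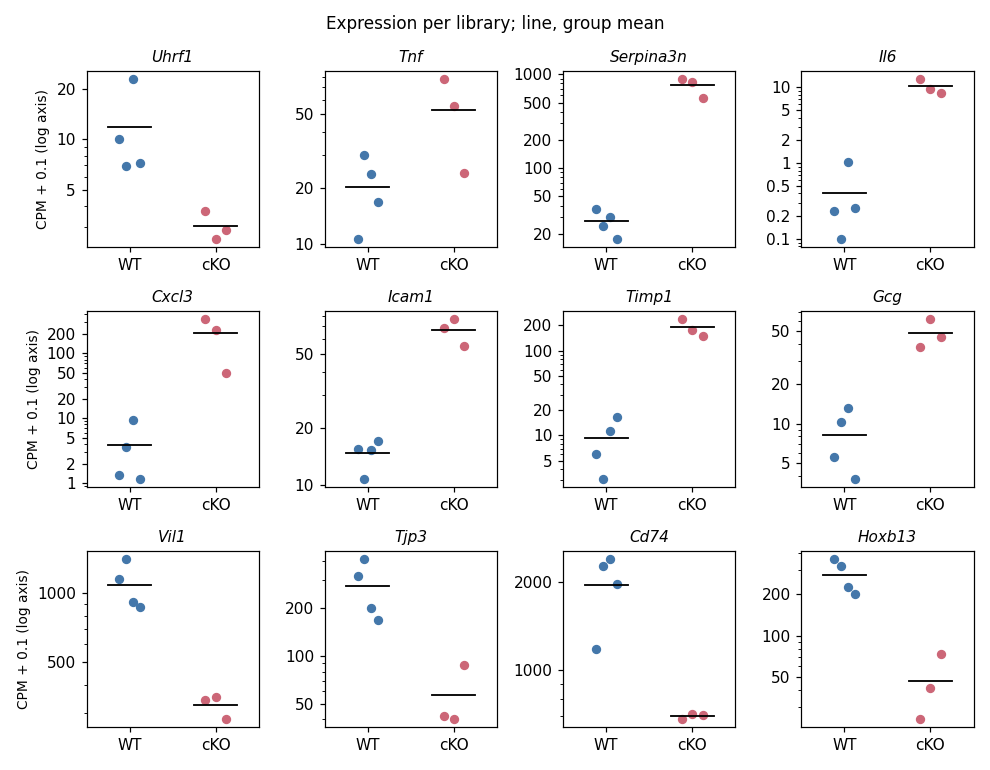
CPM plus 0.1 on a log axis for 12 genes in each library. Points are libraries (blue, 4 wild type; red, 3 conditional knockout) and lines are group means. The groups overlap for Tnf, and for the other 11 genes they do not.

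The inflammatory cytokine, chemokine and NF-kB lists were higher in the conditional knockout by camera with its preset correlation. Of 17 tested members of the inflammatory cytokine list 5 rose and none fell (12 and 1 adjusted over the list alone), with a median log2 fold change of 2.33. Il6 rose from 0.310 ± 0.431 to 10.3 ± 2.36 CPM, Il10, an anti-inflammatory cytokine, from 1.42 ± 0.637 to 16.2 ± 10.1 CPM and Il1a from 4.42 ± 4.74 to 91.4 ± 45.4 CPM. Among 23 chemokines 7 rose (10 adjusted over the list alone). Cxcl3, a neutrophil attractant, went from 3.73 ± 3.78 to 205 ± 145 CPM, Ccl3 from 4.90 ± 5.59 to 117 ± 82.8 CPM and Ccl11, an eosinophil attractant, from 14.6 ± 2.85 to 56.8 ± 25.2 CPM. Of 25 genes of the NF-kB and TNF response 4 rose (6 adjusted over the list alone), among them the adhesion molecule Icam1 (14.6 ± 2.78 to 66.8 ± 11.1 CPM), Ptx3 (0.449 ± 0.331 to 8.96 ± 4.69 CPM) and Ier3 (36.8 ± 10.6 to 194 ± 94.99 CPM). The mean log2 CPM of the NF-kB list was 6.66 and 6.59 in cKO 1 and cKO 3 but 5.48 in cKO 4, below WT 2 (5.71), whereas the cytokine and chemokine means of cKO 4 (3.43 and 4.78), though under those of cKO 1 (4.71 and 5.88) and cKO 3 (4.72 and 5.59), lay above every wild-type library. These lists passed camera at adjusted p = 1.75e-05, 3.51e-05 and 0.000957, and each had an adjusted p = 0.53 with an estimated correlation.

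The neutrophil list and the macrophage and monocyte list were higher by camera with its preset correlation. Of 24 neutrophil genes 3 rose (14 higher and 2 lower adjusted over the list alone), with a median log2 fold change of 2.88. They were Il1r2 (15.3 ± 13.2 to 403 ± 306 CPM), Fpr1 (8.29 ± 6.26 to 97.9 ± 68.6 CPM) and Clec4d (25.9 ± 18.6 to 236 ± 159 CPM). Of 26 macrophage and monocyte genes 2 rose (7 higher and 1 lower adjusted over the list alone), the endotoxin receptor Cd14 (83.3 ± 59.0 to 1389 ± 999 CPM) and Fcgr3 (79.1 ± 14.6 to 275 ± 136 CPM). Cd14 was at 2112 and 1806 CPM in cKO 1 and cKO 3 but 250 CPM in cKO 4, and Fcgr3 at 378, 325 and 121 CPM. Tyrobp did not pass (119.6 ± 35.2 and 394 ± 204 CPM, adjusted p = 0.0511 by edgeR), and the median of the list was 0.37. The macrophage genes Adgre1 and Cd68, chosen after their values were seen, had log2 fold changes of -0.15 and 1.05, and neither passed. The mean log2 CPM of the neutrophil list was 8.03 and 8.06 in cKO 1 and cKO 3 but 5.22 in cKO 4, below WT 2 (6.002) and WT 3 (6.32), and its exact permutation p was 0.171. Camera gave adjusted p = 0.000135 for neutrophil and 0.0177 for macrophage genes, with an adjusted p = 0.58 and 0.53 with an estimated correlation. Without WT 2 or cKO 3 the macrophage list had an adjusted p of 0.0578 and 0.0844.

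The matrix and fibroblast, enteroendocrine and tuft, enteric neuron and glia, and complement and coagulation lists were higher by camera with its preset correlation, though most of their members did not pass. Of 26 extracellular matrix and fibroblast genes 9 rose and none fell (9 adjusted over the list alone), led by the protease inhibitor Timp1 (9.12 ± 6.00 to 188 ± 44.0 CPM) and the matrix metalloproteases Mmp13 (2.82 ± 0.763 to 56.7 ± 32.8 CPM) and Mmp10 (1.03 ± 0.399 to 26.9 ± 16.7 CPM). The other 17 did not pass, with log2 fold changes of 0.16 for Col1a1, -0.07 for Col3a1, -0.10 for Thy1 and -0.07 for Fap. Those of Dcn and Pdgfra, also not passing, were 1.08 and 0.60. All 16 tested enteroendocrine and tuft cell genes had positive fold changes and 6 rose (10 adjusted over the list alone). The 6 included Gcg, the precursor of glucagon-like peptides (8.05 ± 4.24 to 48.5 ± 12.3 CPM), Nts (1.75 ± 1.09 to 12.6 ± 8.75 CPM) and Insl5 (20.5 ± 5.49 to 62.9 ± 27.7 CPM). All 6 are enteroendocrine genes. The tuft cell genes Trpm5, Avil, Dclk1, Sh2d6 and Pou2f3 did not pass. Of 18 enteric neuron and glia genes 1 rose (1 adjusted over the list alone), the receptor gene Ret (3.36 ± 1.79 to 16.5 ± 2.22 CPM), while Gfap (6.65 ± 4.10 and 44.1 ± 42.4 CPM) and Snap25 (2.40 ± 0.795 and 6.11 ± 2.02 CPM) did not pass. None of 19 complement and coagulation genes passed (4 higher adjusted over the list alone) although 18 were positive, with Procr, Plat and Plau at log2 fold changes of 1.66, 2.45 and 1.09. Camera gave adjusted p = 7.35e-06, 2.24e-06, 3.72e-05 and 3.51e-05 for these 4 lists, and each had an adjusted p = 0.53 with an estimated correlation.

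The colonocyte, barrier and junction, and lipid and xenobiotic lists were lower by camera with its preset correlation. Of 25 genes of mature colonocytes 6 fell and none rose (16 adjusted over the list alone), with a median log2 fold change of -1.65. Vil1, which encodes the microvillus protein villin, went from 1088 ± 247 to 326 ± 38.1 CPM, Cdhr5 from 978 ± 217 to 341 ± 65.1 CPM and the carbonic anhydrase gene Car2 from 458 ± 81.5 to 133 ± 71.0 CPM. Of 21 barrier and junction genes 4 fell (12 lower and 1 higher adjusted over the list alone), among them Marveld3 (122 ± 27.2 to 43.1 ± 4.42 CPM), Cldn3 (472 ± 158 to 157 ± 21.9 CPM) and Tjp3 (275 ± 111 to 56.6 ± 27.1 CPM). Of 23 genes of lipid and xenobiotic metabolism 8 fell and 1 rose (13 and 3 adjusted over the list alone). Gsta1 fell from 15.5 ± 4.04 to 2.54 ± 1.35 CPM and Cyp3a13 from 172 ± 50.3 to 38.8 ± 16.4 CPM, whereas Pdk4, a kinase that restrains glucose oxidation, rose from 2.53 ± 0.749 to 10.5 ± 0.696 CPM. Camera gave adjusted p = 5.61e-07, 8.38e-06 and 0.000723, and each list had an adjusted p = 0.53 with an estimated correlation. Over 20 general epithelial genes, a list chosen after the data were seen, the median log2 fold change was -1.32 (-2.44 to 0.19), with 6 lower and 0 higher, so falls of similar size were not confined to mature colonocyte or barrier genes. Hoxb13 fell in the same libraries.

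The oxidative phosphorylation, hypoxia and glycolysis, and proliferation lists were lower by the same test. Of 24 oxidative phosphorylation genes 4 fell (18 lower and 1 higher adjusted over the list alone), including Cox5a (169 ± 33.1 to 66.9 ± 7.71 CPM), Ndufb8 (130.1 ± 9.92 to 80.0 ± 5.28 CPM) and the cytochrome c gene Cycs (492 ± 117 to 219 ± 27.9 CPM). Of 20 hypoxia and glycolysis genes 5 fell and 1 rose (10 and 2 adjusted over the list alone), with falls in Car9 (66.3 ± 22.7 to 14.9 ± 3.72 CPM), Pfkp (350.1 ± 55.2 to 165 ± 12.4 CPM) and Ldha (2063 ± 479 to 811 ± 67.6 CPM). Of 30 proliferation genes 4 fell (10 adjusted over the list alone), among them Mki67 (45.6 ± 32.7 to 9.99 ± 1.49 CPM), Ccna2 (14.0 ± 9.30 to 3.03 ± 0.498 CPM) and Ccnb1 (8.53 ± 6.03 to 1.42 ± 0.474 CPM). WT 3 stood apart in these, with Mki67 at 94.5 CPM against 26.5 to 33.2 CPM in the other wild-type libraries, and without it the log2 fold changes of Mki67 and Ccnb1 went from -2.19 and -2.58 to -1.55 and -1.95. Camera gave adjusted p = 3.08e-08, 0.00173 and 7.35e-06, each with an adjusted p = 0.53 with an estimated correlation. The lower mitochondrial share of counts ran with these groups.

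The dendritic cell and MHC class II list and the B and plasma cell list were lower by the same test. Of 13 dendritic cell and MHC class II genes 4 fell and 1 rose (7 and 1 adjusted over the list alone). The 4 were Ciita, Cd74, H2-DMa and H2-Aa, all of the MHC class II pathway. The 1 that rose was the dendritic cell gene Ccr7 (log2 fold change 2.05). Among other dendritic cell genes Itgax, Flt3 and Zbtb46 had positive and Clec9a and Batf3 negative fold changes, and none of them passed. Ciita, the master regulator of MHC class II, went from 32.4 ± 5.15 to 7.39 ± 5.36 CPM. Without cKO 4, which held 13.6 CPM, the log2 fold change of Ciita went from -2.13 to -2.92. Cd74 went from 1955 ± 544 to 699 ± 15.9 CPM and H2-DMa from 60.1 ± 16.7 to 24.6 ± 5.34 CPM. Epithelial cells can also express these genes during inflammation. The list had an adjusted p = 0.0222 by camera and 0.53 with an estimated correlation, and without WT 3 or WT 4 the camera value was 0.0615 and 0.0668. None of 17 B and plasma cell genes passed (none adjusted over the list alone). Cr2, Jchain and Igha had log2 fold changes of -3.70, -1.32 and -0.93, and the list had an adjusted p = 0.0405 by camera and 0.59 with an estimated correlation. Without WT 1, WT 3, cKO 3 or cKO 4 its camera value was 0.393, 0.0615, 0.0873 and 0.103, and with the stricter filter it was 0.136.

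**Figure D3:**
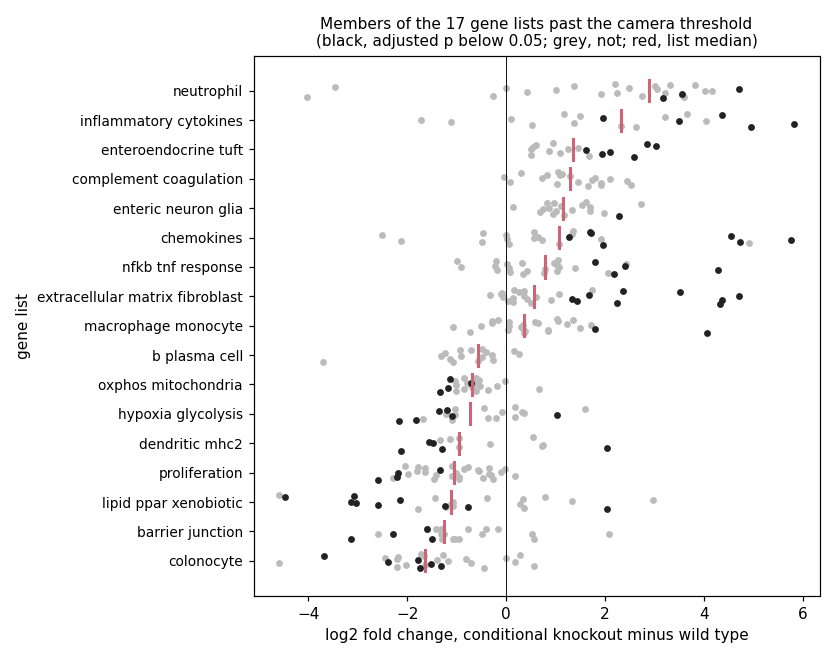
Log2 fold change (conditional knockout minus wild type, horizontal axis) of each tested member of the 17 gene lists past the camera threshold (vertical axis). Black points passed at an adjusted p of 0.05 and grey points did not, and red lines are list medians, from -1.65 for colonocyte to 2.88 for neutrophil genes.

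The largest fall among the named genes was that of S100g, which encodes a calcium-binding protein of absorptive cells, from 80.6 ± 40.1 to 1.35 ± 1.89 CPM (log2 fold change -5.85, SE 1.02, adjusted p = 0.0292 by edgeR). S100g was at 3.52 CPM in cKO 4 against 0.177 and 0.341 CPM in cKO 1 and cKO 3, and without cKO 4 its log2 fold change was -8.27 and Aadac had no counts left in the conditional knockout, so the order of the largest falls depends on that library. The other large falls were in Aadac (-5.08), Svs2 (-4.997), the NADPH oxidase gene Nox1 (-4.96), Pla2g3 (-4.80), Gstm3 (-4.56), Slc34a2 (-4.52), the potassium channel gene Kcnq1 (-4.40), Mettl7a2 (-4.14) and Cyp2c65 (-4.02). Without cKO 4 Slc34a2, Kcnq1, Nox1, Mettl7a2 and Cyp2c65 went to -7.49, -5.97, -5.60, -4.93 and -4.66. Ugt2b35 had 128 counts in wild type and 3 in the conditional knockout, a ratio of 33.1 with a counting interval of 11.1 to 163. Ugt1a1 had 66 and 2 counts, a ratio of 25.6 with an interval of 6.81 to 216, and shares exons with the other genes of its locus.

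The remaining 15 lists did not pass camera. The nearest was regenerating epithelium at an adjusted p of 0.0510, with rises of Krt14 (21.1 ± 4.42 to 60.8 ± 15.5 CPM), Il33 (41.9 ± 20.001 to 164 ± 48.0 CPM) and Spp1 (3.45 ± 3.73 to 43.1 ± 33.7 CPM) among 19 genes (4 adjusted over the list alone). Of 22 antimicrobial genes 2 rose and 2 fell (6 and 5 adjusted over the list alone), with Slpi (425 ± 207 to 2446 ± 652 CPM) and Saa3 (133 ± 103 to 1741 ± 987 CPM) higher and Reg4 lower (30.4 ± 12.5 to 2.86 ± 1.41 CPM). Of 20 members of the goblet cell list 2 rose and 1 fell. Muc2 went from 268 ± 56.0 to 774 ± 345 CPM. Ccl6, also counted in the chemokine list, went from 266 ± 109 to 864 ± 182 CPM, and Muc3 from 2436 ± 995 to 763 ± 85.7 CPM. Of 30 interferon response genes Gbp5 rose (log2 fold change 1.54) and Irf1 fell (-1.30). Single members rose in the lists of crypt stem cells (Smoc2, 3.90), alternatively activated macrophages (Il4ra, 2.14), adipocytes (Lipe, 1.14) and endoplasmic reticulum stress (Chac1, 1.46), and Il5ra (3.94) and Kit (1.43) rose among mast cell and eosinophil genes. No member passed in the lists of endothelium, immediate early genes, DNA methylation machinery, smooth muscle, T and NK cells or erythrocytes. In the pancreas and small intestine list Apob fell (199 ± 64.2 to 53.7 ± 22.8 CPM). Median, mean and test differed in sign in places for the smooth muscle, adipocyte, T and NK cell, alternatively activated macrophage, antimicrobial and goblet lists.

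By camera 9 lists were higher and 8 lower of 32. With an estimated correlation no list passed, and 2 had an unadjusted p under 0.05. By fry, which tests whether the genes of a list move on balance in one direction, 3 passed (colonocyte, enteroendocrine and tuft, chemokines), and 21 passed its test for change in either direction. No list passed the exact permutation test of its mean after adjustment (lowest adjusted p = 0.131), and 5 reached the smallest possible p of 0.0286.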

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

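The tests of the epithelial share, of the cell cycle, of the deletion and of cKO 4 below were chosen after the results they address had been seen. The test of unseen Hox genes was set beforehand.

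In WT 3, several genes lay far from the other wild-type libraries. Ccl3 was at 13.2 CPM there against 1.42 to 3.04 CPM in the others, Ccl4 at 18.5 against 0.946 to 3.62 CPM, and Il6 at 0.948 CPM against at most 0.157 CPM. Mki67 was at 94.5 CPM against 26.5 to 33.2 CPM, and Ccnb1 at 17.6 against 5.20 to 5.68 CPM. In WT 1 the mean log2 CPM of the B and plasma cell list was 4.98 against 3.68 to 3.80 in the other wild-type libraries. These are 6 of 128 values examined for a sample far from its group, in the wild-type libraries alone. Chance alone would give about 6.4 among independent values, but most of these are of chosen genes that move together. Of the 6, all but that of the B and plasma cell list are in WT 3. Xist, which lay outside the comparison, had 2495 counts in cKO 4 and at most 3 in each other library.

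Whether the grouping mattered was tested on all 35 splits of the 7 libraries into 4 and 3. Only the real split, 1 of the 35, called as many as 992 genes by the edgeR quasi-likelihood test. The highest of the 34 others was 0, the outcome written in advance against chance for the gene count. The share of 0.0286 is the smallest that 35 splits allow, so it argues against chance but cannot exclude it. The margin was small before adjustment, since at an unadjusted p under 0.05 the real split gave 4187 genes and the highest other split 3487, and the adjusted count fell to 2 or 3 without WT 1, cKO 1 or cKO 3. The number of gene lists past the camera threshold was 17 for the real split and 8 to 19 for the others, and 6 of the 35 splits reached at least 17. Chance cannot be excluded for the number of lists, and the list calls with the preset correlation carry little weight of their own.

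Hoxb13, Hoxa13 and Hoxd13 were lower in the conditional knockout, with log2 fold changes of -2.59, -1.55 and -1.93, of which Hoxb13 alone passed. Across 20 Hox genes whose values had not been seen, the log2 fold change fell with the paralog number (Spearman rho = -0.69 across genes, permutation p = 0.00111), and genes of one cluster are not independent. This was the outcome written in advance for a more proximal stretch of colon in the conditional knockout samples, which may therefore account for part of the differences in regional epithelial genes. A smaller share of epithelial cells cannot be told apart, since the Hox13 mean relative to 20 general epithelial genes changed by -0.84 but cKO 4 overlapped wild type (exact permutation p = 0.114). The position from which each sample was cut is not given in the sources used here, and a genotype effect on these genes also stays open.

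Lower Uhrf1 in whole colon could reflect fewer cycling cells, as Uhrf1 is a cell cycle gene, or deletion in Lyz2-expressing cells. Relative to the mean of 30 cell cycle genes Uhrf1 changed by -0.84 on the log2 scale (exact permutation p = 0.0571). The groups did not overlap in this measure, at -0.83 to -0.50 in the conditional knockout and -0.24 to 0.51 in wild type. The change lay between the bounds set for the cell cycle alone and against it, and the p did not pass the bound set for deletion. The 2 explanations cannot be told apart here, because some cycle genes went as low as Uhrf1 and the RNA is not from sorted cells. Of the 30 cycle genes 6, not all of which passed, had a log2 fold change at or below that of Uhrf1. The median of the 30 was -1.05, against -1.98 for Uhrf1.

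cKO 4 stood apart from cKO 1 and cKO 3, and over the 1608 genes called without it its median position was 0.455 on a scale from wild type (0) to the other conditional knockouts (1), between the bounds set for and against a mislabelled wild-type library. Of 3 measures added after that, its position over the 500 genes with the smallest p without it was 0.437 (wild-type libraries left out in the same way, at most 0.302), it lay beyond every wild-type library on the knockout side in 80.4% of those genes (WT 3 in 74.0%, the others in 12.4 to 54.8%), and it lay over 4-fold beyond them in 13 of the 24 largest rises and falls chosen without it (wild type 0 to 4). The bounds written for the last 2 measures were met, but were not kept. The share over 500 genes, though above that of every wild-type library, exceeds that of WT 3 by less than the spread between wild-type libraries. The 24 genes chosen without cKO 4 are top genes alone, and some of their values had been seen before the bound was set. With its Uhrf1 (2.81 CPM) also below every wild-type library (6.81 to 22.9), most values argue against a mislabelled wild-type library, which stays open because the test as first written met neither bound. Its deviation correlated at 0.41 with that of the male WT 4, which met the bound of 0.1 written against the sex of the mouse as the cause, but that bound was wrong for this design, since with 1 female library sex and library coincide whatever the correlation, and sex stays open.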

How the results depend on the processing

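Robust moderation, the threshold of 0.1 and leaving out X and Y chromosome genes were added after the data were seen. The alternatives on pseudocounts were planned for FPKM and were not run on counts. Every one of the 992 genes that was tested kept its direction and an unadjusted p under 0.05 under each alternative, and no result reversed. Past the adjusted threshold the total was 2853 with the DESeq2 Wald test (1134 higher, 1719 lower), 4397 with voom quality weights (2096 and 2301) and 2393 at a threshold of 0.1 (1001 and 1392). Without a filter 594 genes were higher. The total stayed between 927 and 1391 with no filter, the stricter filter, the other scalings, robust moderation and the X and Y chromosome genes left out, and scaling moved the median of all genes by less than 0.1. The cause of these differences was not tested. Leaving out 1 library gave totals of 2 to 1608, with 2 to 778 higher and 0 to 830 lower. The lowest came without WT 1 (3), cKO 1 (2) and cKO 3 (3), where 3186, 2809 and 2919 genes had an unadjusted p under 0.05, then without WT 2 (380), and the highest without cKO 4.

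The log2 fold change of Uhrf1 passed at -1.99 without a filter, -2.01 with DESeq2, -1.76 with voom and -1.99 with the replicate block, and ran from -2.18 to -1.43 with a library left out. That of Tnf passed at 1.34 with DESeq2 and 2.04 with voom, and ran from 0.98 to 1.72 with a library left out. With an estimated correlation 0 lists were higher and 0 lower, and with fry 2 were higher and 1 lower. Under the other alternatives 15 to 17 of the 17 list calls held. Of the named genes' values under the alternatives 1037 stayed on their side of the threshold, 342 no longer passed and 29 newly passed. The fold change moved by more than 1.5-fold for 13 of 91 named genes without WT 3, 9 without cKO 4, 8 without cKO 1, 3 without cKO 3, 2 without WT 1 and 0 without WT 2 or WT 4.

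With the replicate number as a block 1393 genes passed, 699 higher and 694 lower, so that 50.2% were higher, and 771 of the 992 were among them. Deviations of samples with the same number correlated at -0.04 for number 1, 0.32 for number 3 and 0.41 for number 4. The values for 3 and 4 are the highest of the 12 between the groups, a hint of something shared, but WT 1 and cKO 1 did not correlate best with each other, and the numbers were not treated as pairs because 1 of the 3 lay under 0.1. In the simulation at this depth and n, which made 53 calls, changes near 2-fold were mostly missed. With more genes changed the threshold is less strict, so the share missed in the real data is not known.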

Other observations

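Grouping genes by the stem of their symbols was done after the data were seen, while the glucocorticoid test was written before its result.

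Among 98 symbol stems with at least 15 tested genes, interleukin and interleukin receptor genes rose more often than other genes (10 of 55, 1.25 expected, Fisher's exact test, adjusted p = 7.44e-05). Among them were Il1r1 (log2 fold change 2.07), Il1rap (2.15), the decoy receptor Il1r2 (4.72) and Il6ra (1.47). Of the Il1 ligands Il1a passed (4.36) and Il1b did not (3.67, adjusted p = 0.0793 by edgeR), and Il6 passed. Il17rc went the other way (-1.79). Matrix metalloproteases rose in 5 of 18 (adjusted p = 0.00193), namely Mmp3, Mmp10, Mmp12, Mmp13 and Mmp14. Il5ra, an eosinophil and B cell receptor, rose from 7.36 ± 5.58 to 113 ± 70.01 CPM, while the eosinophil granule genes Epx and Prg2 did not pass and stood at 2.44 ± 1.89 and 17.2 ± 13.2 CPM in wild type and 0.0620 ± 0.0592 and 2.73 ± 2.17 CPM in the conditional knockout.

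Cytochrome P450 genes fell in 8 of 37 (1.46 expected, adjusted p = 0.00312), including Cyp4f14 (-2.58), Cyp2d12 (-2.19) and Cyp2c68 (-2.64), while Cyp7b1 rose (2.36), and reads may be shared among such paralogs. Myosins fell in 6 of 21 (adjusted p = 0.00397). The microvillus motor Myo1a fell from 509.7 ± 79.9 to 115 ± 35.3 CPM and Myo7b, of the brush border, from 136 ± 39.4 to 35.9 ± 11.2 CPM. None of 349 zinc finger genes with the stem Zfp fell, against 13.8 expected (adjusted p = 0.000107), and 4 rose. Genes are not independent replicates, and these counts rest on the same calls that depend on single libraries.

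Serpina3n, Mt1, Zbtb16 and Pdk4, each of which glucocorticoids induce, were among the clear rises, with Mt1 going from 103 ± 21.3 to 2227 ± 1254 CPM and Zbtb16 from 8.35 ± 1.45 to 32.0 ± 5.20 CPM. The hypothesis of a glucocorticoid response in the conditional knockout was tested on 10 other induced genes. Their median log2 fold change was 1.01, all 10 were positive and 2 passed alone, Cebpd at 1.77 and Tsc22d3 at 1.17. The lowest were Errfi1 at 0.06, Sgk1 at 0.39 and Fkbp5 at 0.50. Camera gave p = 0.000171, the estimated correlation p = 0.149, and the exact permutation test of their mean p = 0.0286, the smallest possible. A stress hormone response may therefore contribute, but the groups also did not overlap for 25.7% of all tested genes, several of these genes also respond to cytokines, and neither hormone levels nor weight loss was analysed here.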
